A study of Homo sapiens with 12 samples.

How the data were processed

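Gene expression was measured on 12 Affymetrix 3' expression arrays, 1 per sample, in K562, an established human leukemia cell line. Per the labels' protocols, all cells were kept in serum-free medium with recombinant Wnt3a at 100 ng/ml, total RNA was taken after 8 h, and 500 ng of it was turned into biotin-labelled cRNA with a 3' in vitro transcription kit. The arrays fell into 4 groups of 3. An empty EGFP vector or a vector for EGFP-tagged CXXC5 was introduced by nucleofection, a transient transfection, and a scrambled shRNA or shRNA against CXXC5 was introduced by stable lentiviral infection. The labels name a pair of CXXC5 shRNA clones without saying which knockdown sample carried which. They do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

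The deposited values are on a log2 scale, 1 value per probe set and array, between 2.07 and 14.4; the log2 scale was inferred from this range, since no header or label states it. Affymetrix Expression Console was used, per the submitters' processing notes, and its version and its summarisation method are not given in the sources used here. The deposited log2 values had array medians between 6.64 and 6.70 over all probe sets, so they had been put on a common scale by the authors before deposit. No scanner files were used here, so background, detection calls and scan batches could not be examined. No dates or batches are given in the sources used here. For arrays there is no depth per sample, and the number of arrays limits the precision.

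Of 22277 probe sets, 62 control probe sets were left out of the tests. A platform annotation table paired 19064 of the remaining probe sets with 1 gene symbol, 1043 with several symbols and 2108 with none. Probe sets with several symbols or none were not named. Symbols were looked up through gene identifiers in a RefSeq gene table (assembly GRCh38.p14), used for names alone, where 19052 probe sets matched by gene identifier and 2 by accession; 10 kept the symbol as given, and 0 symbols changed. For each gene the probe set with the highest mean over the 12 arrays was used, which gave 11963 genes, of which 4310 had more than 1 probe set. Of the probe sets used here, 0 were paired with CXXC5, so its level was not analysed here and the group labels were not checked against it. The array files name no genome build, and no coordinates are given.

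Each gene was fitted with limma 3.58.1 in R 4.3.3, with lmFit and 1 coefficient per group over all 12 arrays, which leaves 8 residual degrees of freedom, followed by eBayes with its default prior. The comparisons were overexpression minus empty vector, knockdown minus scrambled shRNA, the difference of these effects, and scrambled shRNA minus empty vector. The tests were two-sided, and p-values were adjusted over all genes by the Benjamini-Hochberg method. A gene rose or fell where its adjusted p was under 0.05. The 23 gene lists were tested with limma's camera at its preset correlation of 0.01, with adjustment over the 23 lists; an estimated correlation and limma's fry were used as alternatives. The tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. That rule took CXXC5, which has no value here, and, in each of the overexpression and knockdown comparisons, the 10 largest changes each way among genes past the threshold whose groups did not overlap. It added up to 4 changed members of each list, or 2 as values where none passed, the 6 opposite and 4 same-direction genes for which the smaller of both changes was largest, the 3 largest differences of the effects each way and the 5 largest control differences each way. Not every list member taken by that rule is named below.

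The fit was tested on simulated data, with the real genes' means and spread and 200 genes changed by known amounts. The simulated noise was independent between genes and arrays, so effects shared by the genes of an array were not covered. In the simulated overexpression comparison, 22% of genes changed by 0.3 log2 were recovered, 84% at 0.6, and 100% at 1 and at 2, with 9 of 11763 unchanged genes called. In the simulated knockdown comparison the shares were 24%, 76%, 98% and 100%, with 2 unchanged genes called. Alternatives were quantile normalization or median centring of the arrays, a filter on the 40% of genes with the lowest mean, the mean of all probe sets, each probe set on its own, fits on 6 arrays, a trended robust prior, array weights, a replicate block, other thresholds, and leaving out each array in turn. Correlations between replicates of a group were 0.996 to 0.998, and no replicate pair held the same values. Figures were drawn with matplotlib 3.10.9.

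The 3' to 5' difference of the control probe sets served as a sign of RNA and labelling quality. It was 0.87 log2 for GAPDH in scrambled shRNA replicate 3 and 0.227 to 0.335 in the other 11 arrays. For the spiked-in phe control it was 2.68 in that array and 0.159 to 0.593 in the others. For the spiked-in dap control it was 3.81 in that array, 3.14 to 3.59 in the other lentiviral arrays and 2.86 to 3.04 in the 6 transfected arrays, without overlap between the deliveries. The array was kept, and leaving it out of the overexpression fit was an alternative chosen after seeing the data.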

Results

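The arrays asked how raising or lowering CXXC5 changed gene expression in Wnt3a-treated K562 cells. CXXC5 is a zinc finger protein of the CXXC family, known to bind CpG-rich DNA and to inhibit Wnt signalling through Dishevelled. Each of the 4 groups held 3 arrays, and the values are log2 expression values per probe set. All groups received Wnt3a, so no comparison measured the response to Wnt3a itself. None of the probe sets used here was paired with CXXC5, so its level was not analysed here, and groups are called by their labels.

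The groups separated on the first 2 principal components, which held 38.5% and 19.9% of the variance over 11963 genes. The first component ran from the empty vector arrays, at -17.2 to -12.4, to the scrambled shRNA arrays, at 13.8 to 22.9. The overexpression and knockdown arrays lay between them on this component and apart on the second, at -14.5 to -10.9 and at 9.63 to 13.1.

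**Figure D1:**
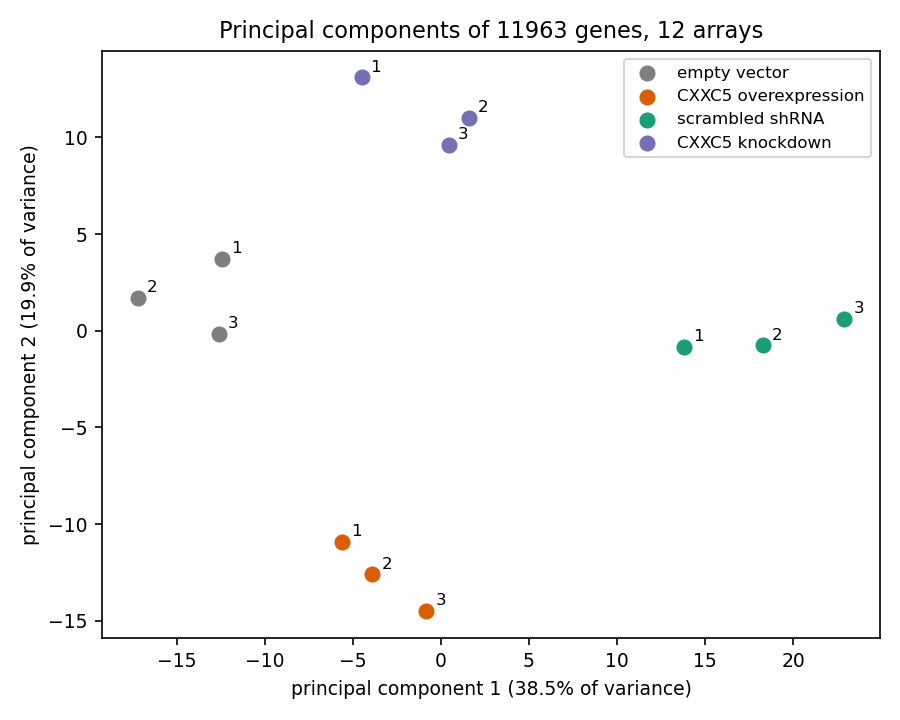
Each point is 1 of the 12 arrays, placed by its scores on principal component 1 (38.5% of variance) and component 2 (19.9%) over 11963 genes; colours are groups and digits are replicate numbers. The 2 control groups, empty vector and scrambled shRNA, lie at opposite ends of component 1.

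With CXXC5 overexpression, the largest change was a fall of the metallothioneins, small cysteine-rich proteins that bind zinc and copper. MT1X was 10.55 ± 0.42 in empty vector and 6.52 ± 0.06 in overexpression arrays (SD, n = 3), a log2 change of -4.03 (SE 0.155, 16.3-fold, adjusted p = 6.7e-08). Log2 changes of the others were -2.91 for MT2A, -2.68 for MT1H, -2.39 for MT1F, -2.35 for MT1G, -2.25 for MT1E and -2.25 for MT1HL1. All 7 values came from probe sets that can match several transcripts of this family, so the separate genes are uncertain. A further MT1G probe set, not of this kind and dim (mean 4.27), stood at -0.14. For these 7 genes the empty vector arrays stood apart from all other groups. The median difference from empty vector was -2.39 with overexpression, -2.21 with scrambled shRNA and -1.99 with knockdown. SLC30A1, which encodes a zinc exporter, fell by 1.63 (SE 0.0852, adjusted p = 7.26e-07). TMEM100 fell by 1.25, and ID3, an inhibitor of DNA binding induced by BMP signalling, fell by 1.18.

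Genes that rose with overexpression included secreted factors and receptors. EGFL6, a secreted protein with EGF repeats, rose by 1.71 log2 (SE 0.0913, 3.27-fold), and PMCH, the precursor of melanin-concentrating hormone, by 1.70 (SE 0.0686). EVI2A, a membrane protein gene within an intron of NF1, rose from 6.67 ± 0.07 to 8.18 ± 0.08 (SD, n = 3), which is 2.84-fold. IER3, an early response gene, rose by 1.47 and LTB, which encodes lymphotoxin beta, by 1.36. The glycoprotein hormone subunit CGA rose by 1.43, the Fc receptor pseudogene FCGR1BP by 1.38, the chemokine CCL20 by 1.22, the TLR4 co-receptor LY96 by 1.19 and the nuclear receptor NR5A2 by 1.18. Adjusted p-values of these 10 genes were at most 0.00221. EGFL6, CCL20, CGA and NR5A2 were dim, between the 12.9th and the 25th percentile of mean level. FCGR1BP is nearly identical to its functional relatives, and its probe set can read these too. The other 2 NR5A2 probe sets stood at 0.27 and 0.54.

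Immediate early genes, which respond within minutes to growth factor signalling, rose together with overexpression: 10 of 31 rose and 0 fell, against 13 and 2 adjusted over the list alone (camera adjusted p = 6.55e-06; adjusted p = 0.271 with an estimated correlation). EGR3 rose by 1.18 log2, EGR1 by 1.08, the ERK inhibitor SPRY4 by 0.87 and PHLDA1 by 0.71. Of 26 NF-kappaB target genes, 5 rose and 2 fell, against 11 and 2 adjusted over the list alone (camera adjusted p = 0.0024; adjusted p = 0.434 with an estimated correlation). IER3 and CCL20 are among those that rose, with IL6 at 0.72, while IRF1 fell by 0.71. These were the 2 lists of 23 past the threshold, while 0 passed with an estimated correlation and 5 with fry. With fry the myeloid and megakaryocyte lists, upward, and the heat shock list, downward, passed as well.

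Wnt target genes did not move as a group with overexpression. Of 18 measured targets, LEF1, a transcription factor of the pathway, rose by 0.28 log2, and BAMBI, a decoy receptor of TGF-beta signalling, fell by 0.28; the counts adjusted over the list alone were also 1 and 1 (camera adjusted p = 0.706). The LEF1 call ended without overexpression replicate 2 and with the mean of its probe sets, and the BAMBI call without any of 5 of the 6 arrays. AXIN2, TCF7, NKD1, ZNRF3 and SP5 were not analysed here. Of 34 Wnt pathway components 1 rose, AXIN1 at 0.29, and 3 fell, FZD3 (-0.56), APC (-0.31) and CTNNB1 (-0.26); over the list alone 1 rose and 5 fell (camera adjusted p = 0.303). Each of these 4 calls ended without at least 3 of the 6 arrays in turn.

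Blood lineage genes changed a few at a time with overexpression. Of 32 erythroid genes 2 rose and 3 fell, against 2 and 4 adjusted over the list alone, with the transferrin receptor TFRC at 0.43 and the embryonic globin HBZ at -0.35. Of 31 myeloid differentiation genes 5 rose and 3 fell, against 8 and 3 over the list alone. The Fc receptor FCGR2A stood at 0.69, NCF1 at -0.49 and the neutrophil protease PRTN3 at 0.47. The NCF1 call ended without any of 4 arrays. Of 23 megakaryocyte genes 1 rose (NRGN, 0.24, a call that ended without any of the 6 arrays) and 0 fell, as also over the list alone. Their camera adjusted p-values were 0.617, 0.0683 and 0.0848. Their fry adjusted p-values were 0.504, 0.0172 and 0.0203, so the myeloid and megakaryocyte lists passed upward with fry but not with camera.

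The remaining 16 lists did not pass camera with overexpression. Of 19 p53 targets, the cell cycle inhibitor CDKN1A rose by 0.53 and PLK2 fell by 0.53; over the list alone 3 rose and 2 fell (adjusted p = 0.745). Of 27 BMP and TGF-beta targets 2 rose and 4 fell, against 4 and 4 over the list alone (camera adjusted p = 0.931). ID3 stood at -1.18, SKIL at -0.83, the signal inhibitor SMAD7 at -0.68 and ID1 at 0.73. The SKIL call ended without any of 3 arrays and the ID1 call without any of 6. The median change of this list was 0.00732 and its mean -0.0304. Of 37 interferon-stimulated genes 2 rose and 3 fell, against 3 and 5 over the list alone, with the chemokine CXCL10 at 0.79 (adjusted p = 0.706). Of 33 ATF4 targets 3 rose and 1 fell, against 3 and 2, with the stress cytokine GDF15 at 0.94 and ATF5 at -0.44 (adjusted p = 0.931). Of 32 hypoxia genes 3 rose and 2 fell, against 5 and 2, with BNIP3L at 0.60 (adjusted p = 0.488). Of 19 heat shock genes 1 rose, HSPA6 at 0.55, and 1 fell, the collagen chaperone SERPINH1 at -0.56, against 1 and 2 (adjusted p = 0.0683). Of 29 apoptosis regulators 3 rose and 1 fell, against 5 and 2, with the caspase-8 inhibitor CFLAR at 0.54 (adjusted p = 0.284). Of 19 unfolded protein response genes 0 rose and 2 fell, against 0 and 4 (adjusted p = 0.152). INSIG1, a brake on sterol synthesis, was the sterol gene that rose, at 0.54, among 21, against 2 up and 1 down over the list alone (adjusted p = 0.153). DNMT3B, a DNA methyltransferase, fell by 0.35, as the single call among 19 CpG-binding factors in either count (adjusted p = 0.31). Of 19 retinoic acid targets NRIP1 was the single call, at -0.25, in either count (adjusted p = 0.827), and it ended without any of 5 arrays. No call was made by limma among 27 G1/S genes, 29 G2/M genes and 39 ribosomal protein genes, nor over each list alone; at unadjusted p under 0.05 there were 3, 3 and 0. SLBP, at -0.20 with adjusted p = 0.0702, BUB1, at -0.23 with adjusted p = 0.079, and RPS3, at 0.06 with adjusted p = 0.544, had the smallest p-values there. The list adjusted p-values were 0.617, 0.871 and 0.745. Of the markers of other cell types, the fibroblast marker FN1 fell by 0.49 as the single call among 30, and PRF1 and CD3D rose by 0.51 and 0.38 among 24 lymphoid markers; counts over each list alone were equal (adjusted p = 0.728 and 0.0683). The CD3D call ended without any of 5 arrays.

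In all, 835 of 11963 genes differed with overexpression, of which 432 rose and 403 fell; the median absolute change of these was 0.372 log2. Of these, 27 changed at least 2-fold, 16 up and 11 down. The groups did not overlap for 27.9% of genes, against 10% by chance. The count rested on single arrays: it was 380 without empty vector replicate 2, 468 without overexpression replicate 2 and 470 without overexpression replicate 3. The 51.7% of calls that were up became 44.4% (488 up, 612 down) without the 40% of genes with the lowest mean and 63.4% (298 up, 172 down) without overexpression replicate 3, so neither direction held a stable majority.

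In the knockdown arrays, chemokine and cytokine genes under NF-kappaB control were far below their level with scrambled shRNA. CXCL1, a neutrophil chemokine, was 9.35 ± 0.17 with scrambled shRNA and 5.70 ± 0.28 with knockdown (SD, n = 3), a log2 change of -3.65 (SE 0.138, 12.5-fold, adjusted p = 2.16e-08). LTB (-3.16), CXCL10 (-2.89), CXCL2 (-2.48), CXCL3 (-2.38), CXCL8 (-2.22), the adhesion receptor ICAM1 (-1.75) and CCL4 (-1.74) also fell; a dimmer ICAM1 probe set stood at -0.71. Of 26 NF-kappaB target genes 19 fell and 1 rose, against 19 and 2 adjusted over the list alone (camera adjusted p = 2.6e-19; adjusted p = 0.0156 with an estimated correlation). Of 31 immediate early genes 19 fell and 1 rose, against 21 and 2 over the list alone (camera adjusted p = 3.17e-15; adjusted p = 0.0156 with an estimated correlation). Among the immediate early genes, EGR3 (-2.04), the mRNA decay factor ZFP36 (-1.36), EGR1 (-1.31) and SPRY4 (-0.995) fell. IER3, a member of the NF-kappaB list, fell by 2.02. Scrambled shRNA replicate 3, the array with weak 5' control signal, belongs to this comparison. Without it, the median change was -0.784 over the NF-kappaB list and -0.392 over the immediate early list, against -0.733 and -0.435 with it.

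Endoplasmic reticulum chaperones rose with knockdown. Of 19 unfolded protein response genes 11 rose and 0 fell, against 14 and 0 over the list alone (camera adjusted p = 6.59e-10; adjusted p = 0.0156 with an estimated correlation). The chaperone HSPA5 rose by 0.85 log2, SDF2L1 by 0.83, the disulfide isomerase PDIA4 by 0.68 and HYOU1 by 0.56. Scrambled shRNA arrays were lower than empty vector arrays in 9 of these 19 genes and higher in 1. Against empty vector, in a comparison chosen later, 6 rose with knockdown and 1 fell (camera adjusted p = 1.2e-05, and 0.0808 with an estimated correlation). Hypoxia and glycolysis genes fell, 9 of 32 with 1 rise, against 12 and 1 over the list alone (camera adjusted p = 0.00116; adjusted p = 0.506 with an estimated correlation). The vasodilator peptide ADM (-0.86), the mitophagy receptors BNIP3L (-0.53) and BNIP3 (-0.42) and the glucose transporter SLC2A3 (-0.48) fell. In knockdown minus empty vector, a comparison chosen later, 7 of these 32 genes rose and 0 fell (camera adjusted p = 7.15e-05, and 0.376 with an estimated correlation). The direction of the hypoxia list thus depended on the control. Of 29 G2/M genes 5 rose and 1 fell, against 7 and 2 (camera adjusted p = 0.0289; adjusted p = 0.536 with an estimated correlation). CDC20 rose by 0.36 and cyclin B1 (CCNB1) by 0.26. The G2/M list did not pass without scrambled shRNA replicate 2 or 3 or knockdown replicate 1, nor after quantile normalization or the filter on low levels.

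Single genes that rose most with knockdown came from several families. SSH1, a cofilin phosphatase, rose by 1.31 log2 (SE 0.122), and the zinc finger gene ZNF22 by 1.24 (SE 0.0737), from 8.71 ± 0.05 to 9.95 ± 0.05 (SD, n = 3). PTPN22, a tyrosine phosphatase, rose by 1.18, SLC30A1 by 1.18, LBH by 1.17, the histamine-degrading enzyme HNMT by 1.10, the kinase NEK3 by 1.09 and PIR by 1.05. SELENOT rose by 1.08 (SE 0.272, adjusted p = 0.0202), a call that ended without knockdown replicate 2 or 3, and by 0.63 without scrambled shRNA replicate 3. THBS1, which encodes thrombospondin 1, rose by 1.53 at its brightest probe set (SE 0.192), but its other 4 probe sets stood at -0.14 to 0.38. Other HNMT probe sets stood at -0.11 to 0.28, the other 2 of PTPN22, both dim, at 0.37 and -0.02, and the other of NEK3 at 0.55. Each of these genes except PIR was also lower in scrambled shRNA than in empty vector arrays, from -0.89 for LBH to -1.58 for PTPN22. Means in empty vector and knockdown arrays were 8.00 and 8.05 for SSH1, 9.84 and 9.95 for ZNF22, and 6.57 and 6.59 for NEK3. They were 6.49 and 6.09 for PTPN22, 6.75 and 6.36 for HNMT, and 7.93 and 8.67 for PIR.

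Wnt target genes did not move as a group with knockdown. Of 18 targets, CD44 rose by 0.30 and BAMBI by 0.30, while FOSL1 (-0.48) and LEF1 (-0.24) fell; counts over the list alone were the same 2 and 2 (camera adjusted p = 0.458). The CD44, BAMBI and FOSL1 calls each ended without at least 3 of the 6 arrays in turn, and the LEF1 call with the mean of its probe sets. Of 34 Wnt pathway components 5 rose and 3 fell, against 7 and 3 over the list alone (camera adjusted p = 0.458, fry adjusted p = 0.0481). The receptor FZD3 rose by 0.83, FZD2 by 0.48 (a call lost without any of 3 arrays) and the tumour suppressor APC by 0.42, while AXIN1 fell by 0.48. In scrambled shRNA minus empty vector, 2 of the 34 were higher and 10 lower (camera adjusted p = 0.188, fry adjusted p = 0.00371), with FZD3 at -0.92. In knockdown minus empty vector, a comparison chosen later, 1 of the 34 rose and 0 fell (camera adjusted p = 0.206). DNMT3B rose by 0.50, TET1 by 0.48 and MBD2 by 0.33 among 19 CpG-binding and DNA methylation factors, with 0 falls and the same counts over the list alone (adjusted p = 0.492).

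Red cell genes moved both ways with knockdown, 5 up and 6 down of 32, against 6 and 6 over the list alone (camera adjusted p = 0.45). The haem synthesis enzyme ALAD rose by 0.60 and the regulator GATA1 by 0.47, while the globin HBE1 (-0.56) and ALAS2 (-0.49) fell. Of 23 megakaryocyte genes 3 rose and 1 fell, against 3 and 2 (adjusted p = 0.514), with CD9 at 0.60, or 0.40 without scrambled shRNA replicate 3. Of 31 myeloid genes 1 rose and 4 fell, in either count, with CEBPA at 0.43 and FCGR2A at -0.47 (adjusted p = 0.272). Of 19 p53 targets 5 rose and 4 fell, in either count, with TIGAR at 0.75 and CDKN1A at -0.84 (adjusted p = 0.75). Of 27 G1/S genes 2 rose and 4 fell, against 2 and 5, with RRM2 at -0.48 (adjusted p = 0.317). Of 27 BMP and TGF-beta targets 4 rose and 3 fell, against 4 and 4, with SKIL at 1.03, ID3 at 0.89 and JUNB at -0.90 (adjusted p = 0.347). Of 37 interferon-stimulated genes 2 rose and 3 fell, against 4 and 4, with RSAD2 at 0.71 (adjusted p = 0.998). Of 33 ATF4 targets 5 rose and 3 fell, against 6 and 8, with GDF15 at -1.29 and ATF5 at 0.44 (adjusted p = 0.492). Of 19 heat shock genes 2 rose and 2 fell, against 4 and 3, with SERPINH1 at 0.58 and HSPA1L at -0.54 (adjusted p = 0.514). Of 21 sterol synthesis genes 1 rose and 5 fell, against 2 and 5, with INSIG1 at -0.73 and MSMO1 at -0.46 (adjusted p = 0.0668). Of 29 apoptosis regulators 1 rose and 5 fell, against 2 and 5, with BAD at 0.50 and CFLAR at -0.80 (adjusted p = 0.177). Of 19 retinoic acid targets 2 rose and 1 fell, in either count, with NRIP1 at 0.57 (adjusted p = 0.75). No ribosomal protein gene of 39 was called by limma, also over the list alone or at unadjusted p under 0.05, and RPLP2 stood at -0.31 with adjusted p = 0.241 (list adjusted p = 0.0668). Of other cell types' markers, 3 of 30 epithelial and fibroblast genes fell, among them FN1 (-0.65), and 2 of 24 lymphoid genes fell, CD3D (-0.35) and PRF1 (-0.34); counts over each list alone were equal (adjusted p = 0.144 and 0.0668). The CD3D and PRF1 calls each ended without any of 5 arrays. Median and mean change had opposite signs for the megakaryocyte list (-0.0881 and 0.0136), the interferon list (0.0193 and -0.0243) and the CpG-binding list (-0.0061 and 0.0572).

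In all, 1677 genes differed with knockdown, 1052 up and 625 down, with a median absolute change of 0.357 log2, and 36 changed at least 2-fold, 14 up and 22 down. The 62.7% of calls that were up became 48.9% (849 up, 886 down) when each array was centred on its median. The groups did not overlap for 32.4% of genes, against 10% by chance. A fit on the 6 arrays alone called 1018 genes.

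**Figure D2:**
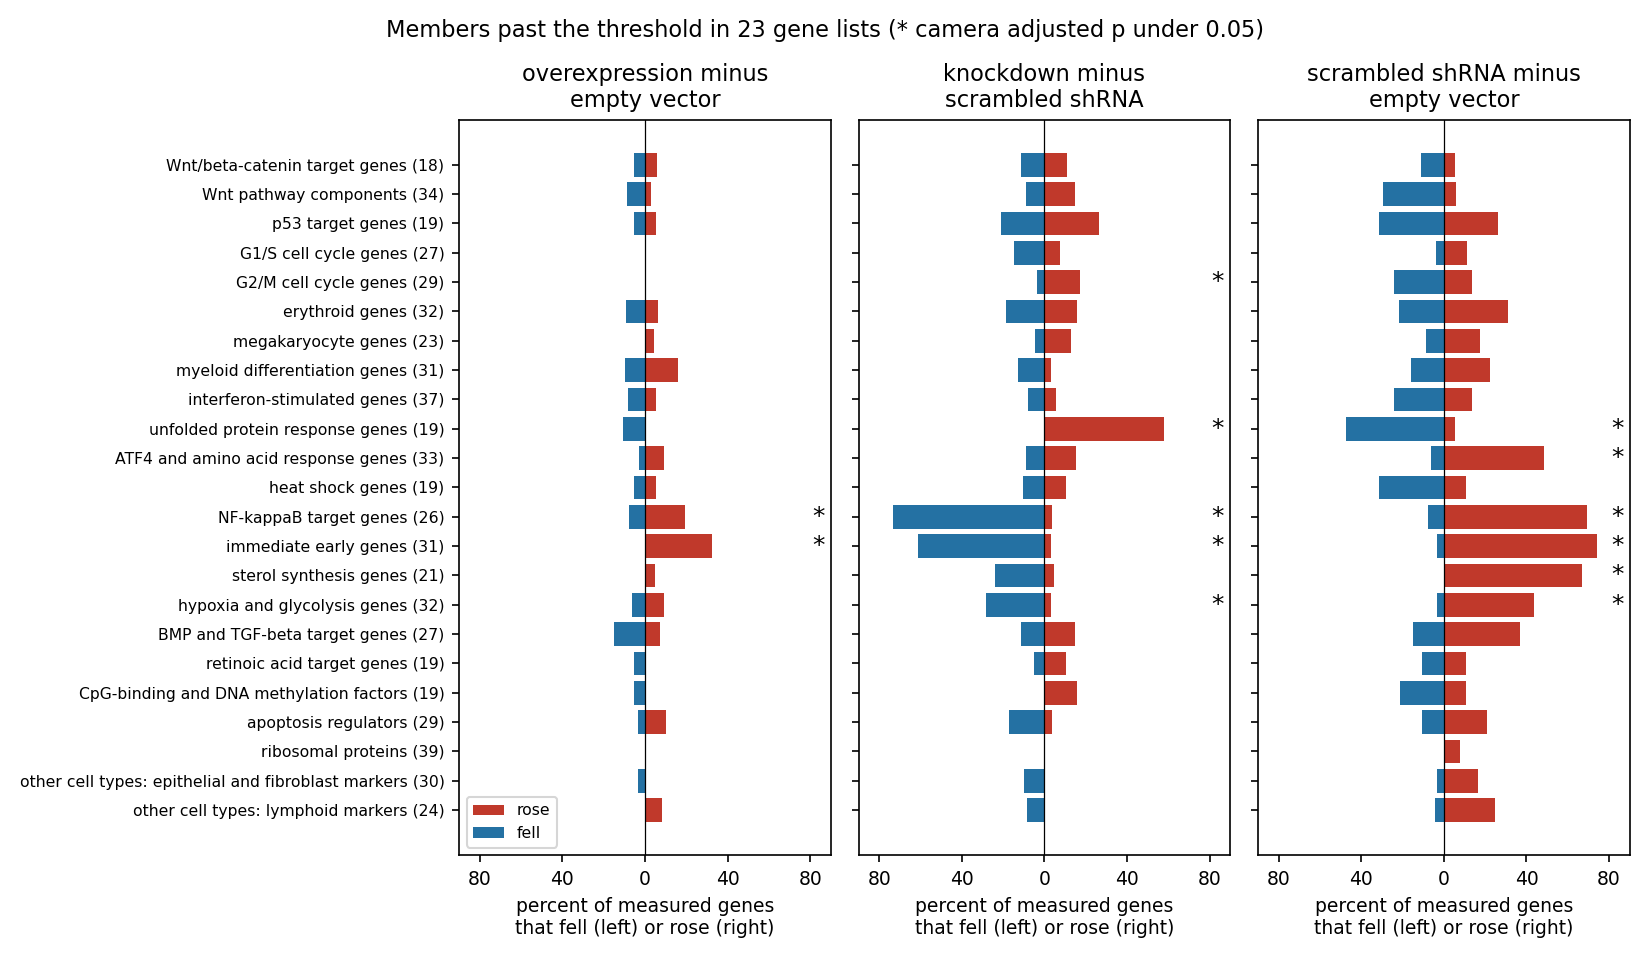
Bars give the percent of each list's measured genes (number in brackets) that rose, to the right, or fell, to the left, at limma adjusted p under 0.05, in 3 comparisons; asterisks mark lists with a camera adjusted p under 0.05. The NF-kappaB list shows 5 rises of 26 with overexpression, 19 falls with knockdown and 18 rises in scrambled shRNA against empty vector.

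The overexpression and knockdown effects opposed each other across many genes. Of 511 genes past the threshold in both comparisons, which share no arrays, 504 moved in opposite directions and 7 in the same direction. Independent lists of these lengths would share 58 and 59. Of the opposite genes, 227 rose with overexpression and fell with knockdown, and 277 did the reverse; together they were 60.4% of the genes called with overexpression. Across the 11963 genes, which are not independent replicates, the log2 changes had a Pearson r of -0.547 and a Spearman rho of -0.539. The opposite count was 262 without empty vector replicate 2, 297 without overexpression replicate 2, 306 without overexpression replicate 3, and 591 without scrambled shRNA replicate 3.

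IER3, LTB, EGR3 and EGR1 rose with overexpression and fell with knockdown. SLC30A1 did the reverse. ZNF143, a zinc finger transcription factor, rose by 1.08 log2 with overexpression and fell by 1.06 with knockdown (SE 0.0838 for each), although its dimmer probe set stood at 0.02 and -0.17. Its group means were 8.78 in empty vector, 9.86 in overexpression, 9.85 in scrambled shRNA and 8.79 in knockdown arrays. ZNF22 had the inverse grouping, high in empty vector and knockdown arrays, with means of 9.84, 8.86, 8.71 and 9.95 for the same sequence of groups. CALB1, a calcium-binding protein, rose in both comparisons, by 0.85 and 0.75, as did HNMT, by 0.55 and 1.10, and LY96, by 1.19 and 0.65. The LY96 call with knockdown ended without any of 4 of the 6 arrays in turn. The tubulin gene TUBB2B fell in both, at -0.60 and -0.68. Set against empty vector, knockdown arrays lay the other way for each of these genes. Means in empty vector and knockdown arrays were 6.70 and 6.16 for CALB1, and 6.75 and 6.36 for HNMT. They were 6.08 and 5.37 for LY96, and 7.89 and 8.21 for TUBB2B. Scrambled shRNA arrays lay further from empty vector, at 5.41, 5.26, 4.72 and 8.89 in the same gene sequence.

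**Figure D3:**
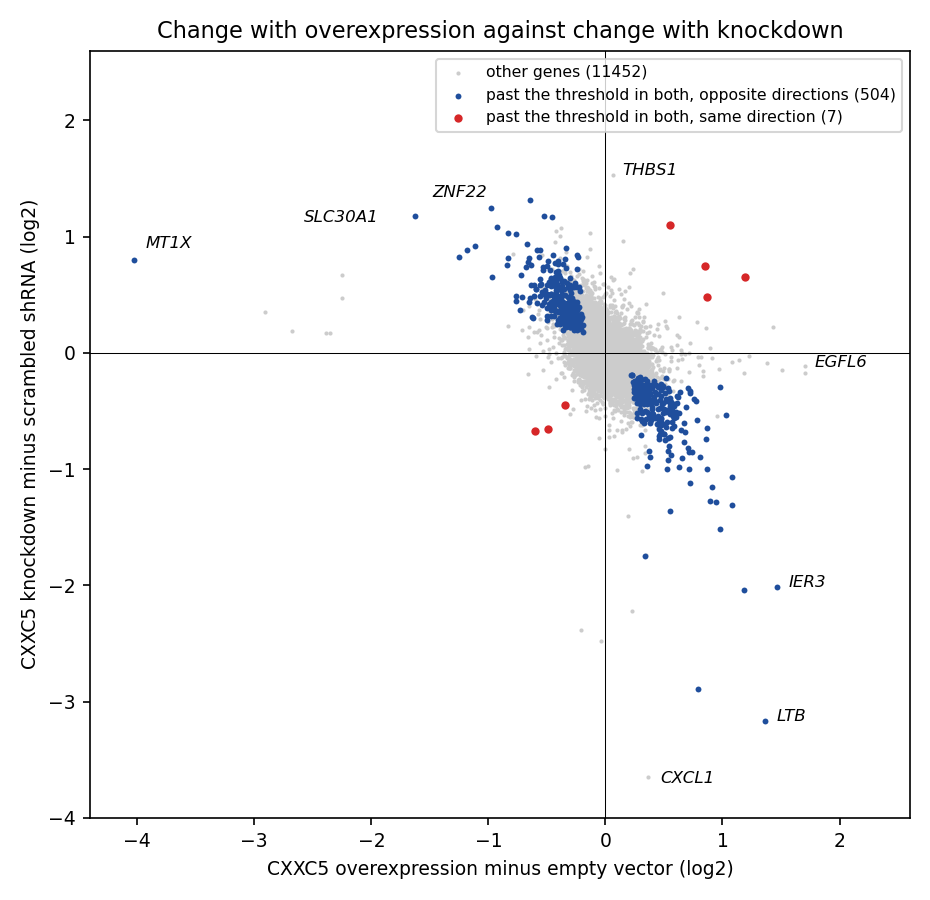
Each point is 1 of 11963 genes, with its log2 change with overexpression on the horizontal axis and with knockdown on the vertical axis. Blue points are the 504 genes past the threshold in both comparisons in opposite directions, and red points the 7 in the same direction.

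Tested directly, the effects differed for 2442 genes, of which 975 had the more positive change with overexpression and 1467 with knockdown. The 39.9% that were more positive with overexpression became 51.4% (1274 against 1205 genes) after median centring. LTB differed by 4.53 log2, CXCL1 by 4.01 and CXCL10 by 3.68. In the other direction, MT1X differed by -4.83, MT2A by -3.26 and MT1E by -2.92. The adjusted p-values of these 6 genes were at most 5.96e-05.

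The control groups, which differ in vector and in delivery, were also compared. The 3' to 5' difference of the spiked-in dap control differed between the deliveries too, at 2.86 to 3.04 log2 in the 6 transfected and 3.14 to 3.81 in the 6 lentiviral arrays. Scrambled shRNA arrays were higher than empty vector arrays in CXCL1 by 3.49 log2, LTB by 3.16, CXCL8 by 2.94, CXCL2 by 2.32 and CXCL10 by 2.27. They were lower in MT1X (-3.31), MT1E (-2.58), MT2A (-2.46), MT1H (-2.21) and MT1G (-2.17). Of 26 NF-kappaB targets 18 were higher and 2 lower, against 18 and 2 adjusted over the list alone, and of 31 immediate early genes 23 were higher and 1 lower, against 24 and 2. Each of these lists had camera adjusted p = 9.19e-12, and adjusted p = 0.0458 with an estimated correlation. Without scrambled shRNA replicate 3, the median difference was 0.718 over the NF-kappaB list and 0.445 over the immediate early list, against 0.758 and 0.448 with it.

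Sterol synthesis genes were higher with scrambled shRNA, 14 of 21 with 0 lower, against 15 and 2 over the list alone (camera adjusted p = 8.84e-07; adjusted p = 0.0625 with an estimated correlation). INSIG1 differed by 1.24, MSMO1 by 0.92 and HMGCS1 by 0.80. Hypoxia genes were higher, 14 of 32 with 1 lower, against 16 and 1 (camera adjusted p = 4.82e-06; adjusted p = 0.312 with an estimated correlation), with ADM at 1.56 and VEGFA at 1.11. ATF4 targets were higher, 16 of 33 with 2 lower, against 19 and 2 (camera adjusted p = 1.14e-05; adjusted p = 0.333 with an estimated correlation), with GDF15 at 2.09 and DDIT3 at 1.10. Of 19 unfolded protein response genes 9 were lower and 1 higher, in either count (camera adjusted p = 0.0327; adjusted p = 0.333 with an estimated correlation), with SDF2L1 at -0.69. The other 17 lists did not pass camera at its preset correlation. Of the 23 lists, 2 passed with an estimated correlation and 18 with fry. In all, 3768 genes (31.5%) differed between the controls, 1935 higher and 1833 lower with scrambled shRNA, and the groups did not overlap for 45.7% of genes, against 10% by chance. The 51.4% of calls that were higher became 60.5% (2340 higher, 1530 lower) after median centring and 44.9% (1467 higher, 1803 lower) without the 40% of genes with the lowest mean.

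**Figure D4:**
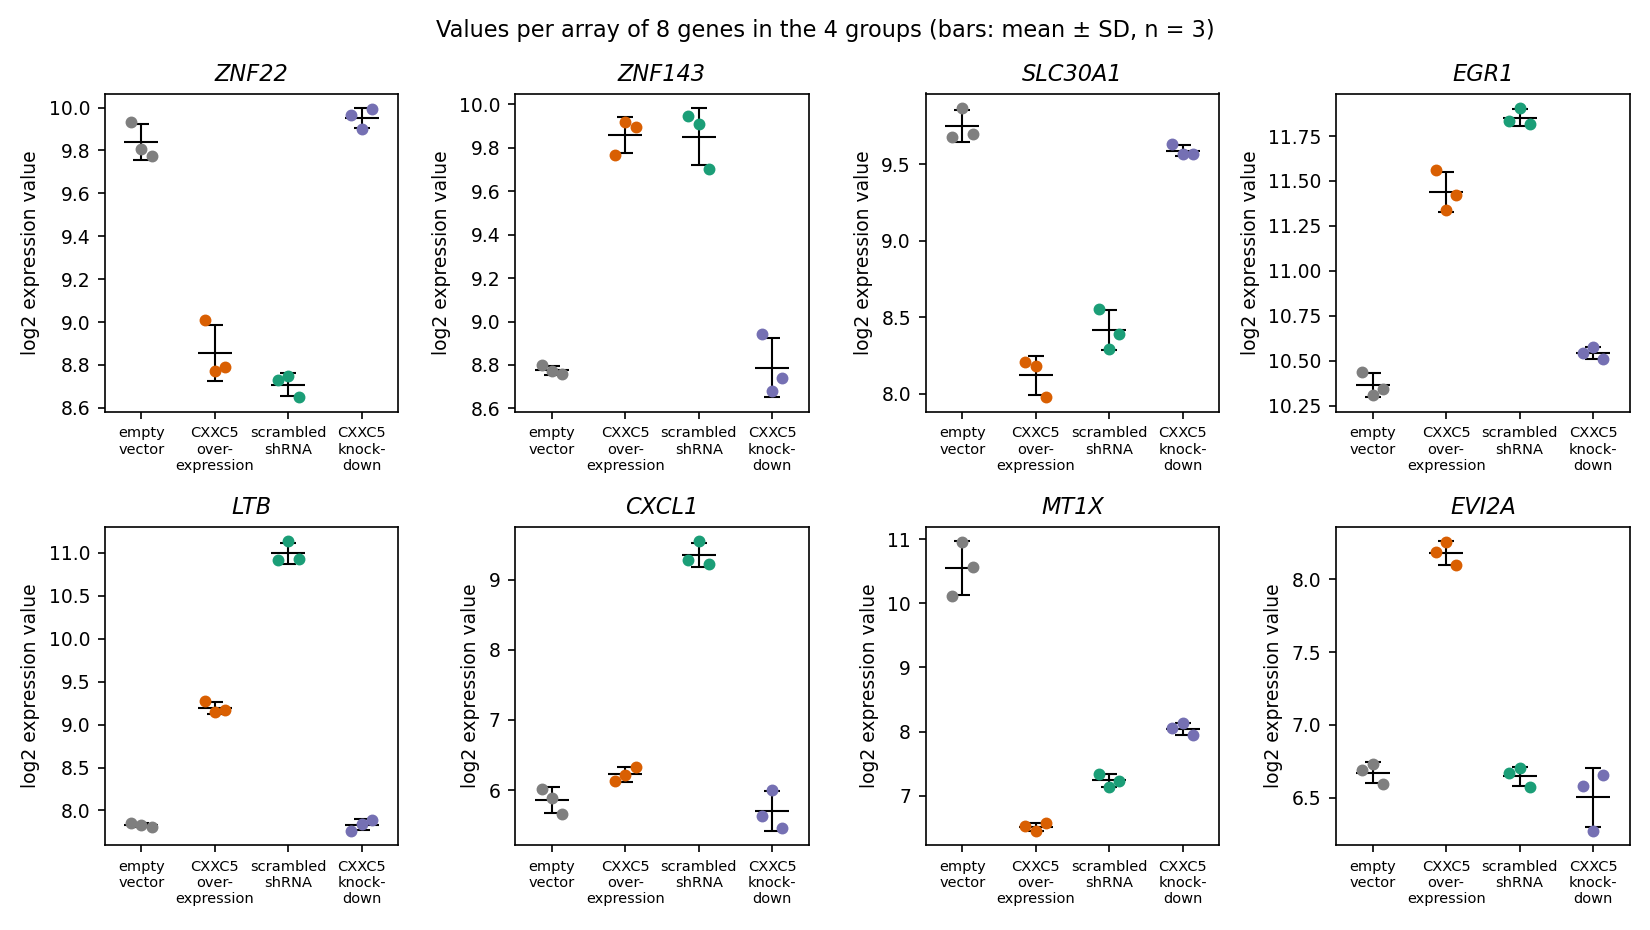
Points are log2 expression values per array for 8 genes in the 4 groups, with bars for mean ± SD (n = 3); each panel has its own axis, which does not start at 0. ZNF22, ZNF143 and SLC30A1 have like levels in empty vector and knockdown arrays, CXCL1 and LTB are highest with scrambled shRNA, MT1X with empty vector and EVI2A with overexpression.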

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

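The test of the difference, the regroupings of arrays and the fits without 1 array were planned; the other tests of explanations for the 3 patterns, and the use of these fits as such tests, were chosen after the results were seen. The effects of overexpression and knockdown differed for 2442 genes in a test of the difference itself. The 6 named differences were LTB at 4.53 log2, CXCL1 at 4.01, CXCL10 at 3.68, MT1X at -4.83, MT2A at -3.26 and MT1E at -2.92. Of 100 regroupings of the arrays within the overexpression and knockdown comparisons, drawn from 200, 1 gave as many genes, the real grouping itself, and the highest other gave 218. For the 504 opposite genes it was also 1 of 100, with 0 as the highest other, and for the correlation of -0.547 it was 1 of 100, with -0.4 as the most negative other. The real grouping was thus the most extreme of those drawn for each result. Wrong splits of either comparison called at most 1 gene, so the 0 opposite genes in other regroupings were nearly fixed in advance. Chance differences between cultures are not excluded, since replicates may be technical. For the overexpression count (835, highest other split 1), the knockdown count (1677, highest other 0) and the control count (3768, highest other 0), 10 splits of 6 arrays are too few for a share under 0.05; in each, 1 split, the real one, reached the count. For gene lists, splits other than the real one also reached the counts. At least the 2 lists of the overexpression comparison came from 5 of 10 splits (highest other 6). At least the 5 of knockdown came from 3 splits (highest other 6), and at least the 6 of the controls from 3 (highest other 7). The number of lists past the threshold therefore does not speak against chance arrangement of the arrays.

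The first pattern is the set of 504 genes with opposite changes, whose levels with scrambled shRNA lay on the overexpression side of empty vector for 500 of them. If only the dose of CXXC5 acted, from a level shared by both control groups, scrambled shRNA and empty vector should be alike in these genes. In array pairs left out when the genes were chosen, scrambled minus empty vector, signed by the overexpression effect, instead had a median of 0.559 log2 (0.483 to 0.655 over 3 pairs), which argues against that model as the whole cause. The weak 5' control signal of scrambled shRNA replicate 3 is also argued against as the source, since 591 opposite genes were found without that array. Exchanged labels, or a culture difference that groups empty vector with knockdown and overexpression with scrambled shRNA, stay open, because CXXC5 was not measured; 67 of the 504 genes passed the threshold in knockdown minus empty vector and 170 in overexpression minus scrambled shRNA, so neither pair was fully alike. A lower CXXC5 level in empty vector cells than in scrambled shRNA cells is a biological explanation that may hold and was not tested.

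The second pattern is the high level of NF-kappaB target and immediate early genes in the scrambled shRNA arrays. The NF-kappaB list mean was 0.915 log2 (SE 0.043) above empty vector, and the immediate early mean 0.568 (SE 0.022), which argues against knockdown lowering these genes from a level that both controls shared. The median NF-kappaB difference was 0.718 without scrambled shRNA replicate 3, which argues against that array as the cause. Lentiviral delivery alone should raise both lentiviral groups, but the NF-kappaB mean in knockdown was -0.00487 (SE 0.039) from empty vector. Of the 26 targets 2 rose and 0 fell in that comparison. CXCL8 was 8.85 in empty vector, 9.57 in knockdown and 11.79 in scrambled shRNA arrays. The immediate early mean in knockdown was 0.0928 (SE 0.034) above empty vector. A small part by delivery thus stays open for the immediate early genes and for single NF-kappaB targets. A response to the scrambled shRNA cultures that CXXC5 knockdown prevents, and a culture difference peculiar to the scrambled shRNA cells, may each be the source and were not tested.

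The third pattern is the metallothionein genes, high in the empty vector arrays. Their median in scrambled shRNA was -2.21 log2 from empty vector, against -2.39 with overexpression, so a CXXC5 dose acting from a shared control level is argued against. How many separate genes fell cannot be told apart from shared hybridization, since 7 of 7 values come from probe sets that can match several transcripts; a further MT1G probe set, not of this kind, stood at -0.14 with overexpression and 0.21 between the controls, but it is dim (mean 4.27). A difference in metal supply of the empty vector cultures may be a source and stays open, since 1 further gene cannot decide it. SLC30A1, which responds to zinc through the same factor, was -1.63 with overexpression and -1.33 with scrambled shRNA, each minus empty vector. In knockdown minus empty vector it was -0.158 (SE 0.0852, limma adjusted p = 0.294), while the metallothionein median there was -1.99. Overexpression, scrambled shRNA and knockdown arrays all lay below empty vector, so the metallothionein levels did not follow the CXXC5 labels alone. Any other effect of CXXC5 on these genes stays open, as untested.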

How the results depend on the processing

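The CXXC5 results have no value under any setting, because 0 of the probe sets used here were paired with it. For named genes, with or without a call, 1477 results from leaving out 1 array stayed on their side of the threshold and 251 calls were lost; under other settings 2104 stayed, 89 calls were lost, 7 were gained and 2 results turned. The turned results were CCNE2 (-0.21, adjusted p = 0.119) and CD44 (0.13, adjusted p = 0.279) in scrambled minus empty vector, with the mean of all probe sets. With each array left out in turn, 49 of 75 named calls with overexpression, 76 of 99 with knockdown, 77 of 94 between the controls and 6 of 6 differences held. Below, the cause was not tested unless given.

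For overexpression, 835 genes became 326 at adjusted p under 0.01, 133 at 1.5-fold or more and 27 at 2-fold or more, and 1550 with array weights. Leaving out 1 array gave 380 to 1060; the highest was without scrambled shRNA replicate 3, tried after seeing the data, where 829 of the 835 genes were shared. It was 380 without empty vector replicate 2, 468 without overexpression replicate 2 and 470 without replicate 3. For knockdown, 1677 became 783, 213 and 36 at these thresholds and 1018 on its own 6 arrays, where fewer degrees of freedom remain; leaving out 1 array gave 1134 to 1529. For the difference, 2442 became 1344, 931 and 217, and leaving out 1 array gave 1864 to 2421. For the controls, 3768 became 2086, 550 and 96, and 6157 when every probe set was tested and counted on its own; leaving out 1 array gave 2593 to 3586.

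The 504 opposite genes became 760 without the 40% of genes with the lowest mean, 307 when each comparison used its own 6 arrays, 893 with array weights, 187 at adjusted p under 0.01 and 1394 at unadjusted p under 0.05. Leaving out 1 array gave 262 to 591, with 262 without empty vector replicate 2, 297 without overexpression replicate 2 and 306 without replicate 3. The correlation stayed within -0.554 to -0.492 when 1 array was left out. The 2 lists of overexpression became 4 with the mean of all probe sets, 4 with the trended robust prior, 0 with an estimated correlation and 5 with fry, which asks another question. Leaving out 1 array gave 2 to 6 lists, with 6 without empty vector replicate 3 and 5 without overexpression replicate 1. The 5 lists of knockdown became 3 with an estimated correlation and 11 with fry, and 4 to 6 with 1 array left out.

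Replicate numbers are shared between groups, but the block on them is only a check: same-numbered arrays correlated at 0.28, -0.014 and 0.33 between empty vector and overexpression, and at 0.27, -0.034 and 0.045 between scrambled shRNA and knockdown, and 6 of 12 arrays correlated best with their own number. With the replicate block the counts were 789, 1817, 2575 and 4047 for overexpression, knockdown, difference and controls, 495 opposite genes, and 3 and 6 lists. Signal over background was not available, and changes of dim genes may be understated.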

Other observations

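The tests in this part were chosen after the main results were seen, except the last, whose prediction was written before its count. Each manipulated group was also set against the other control, from which it differs in delivery as well. Knockdown minus empty vector called 543 genes, 361 up and 182 down, fewer than knockdown minus scrambled shRNA (1677). The collagenase MMP1 rose by 1.24 log2 (SE 0.15), the spermidine acetyltransferase SAT1 by 0.98 and the Notch target HEY1 by 0.93. Metallothioneins were 7 of the 8 largest falls there, led by MT1X (-2.50) and MT2A (-2.11). Of 21 sterol synthesis genes 10 rose and 0 fell (camera adjusted p = 2.06e-10; adjusted p = 0.0284 with an estimated correlation), and of 33 ATF4 targets 11 rose and 0 fell (camera adjusted p = 2.82e-10; adjusted p = 0.166 with an estimated correlation). Interferon-stimulated genes fell, 4 of 37 with 0 rises (camera adjusted p = 0.000161; adjusted p = 0.0284 with an estimated correlation). Of 19 unfolded protein response genes 6 rose and 1 fell (camera adjusted p = 1.2e-05; adjusted p = 0.0808 with an estimated correlation), and of 32 hypoxia genes 7 rose and 0 fell (camera adjusted p = 7.15e-05; adjusted p = 0.376 with an estimated correlation). The G1/S list (1 rise, 2 falls; camera adjusted p = 0.00188) and the heat shock list (no calls by limma; camera adjusted p = 0.0312) also passed downward, with adjusted p = 0.292 and adjusted p = 0.391 with an estimated correlation. NF-kappaB targets had 2 rises and 0 falls of 26 there (camera adjusted p = 0.537). These genes were named by size after their values were seen.

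Overexpression minus scrambled shRNA called 2154 genes, 976 up and 1178 down. LY96 rose by 2.55 log2, PMCH by 2.23, CALB1 by 2.14 and HNMT by 2.04, while CXCL1 fell by 3.13 and CXCL8 by 2.71. NF-kappaB targets fell, 20 of 26 with 2 rises, and immediate early genes fell, 21 of 31 with 0 rises (adjusted p = 0.0378 for each with an estimated correlation). So the direction of the NF-kappaB change with overexpression depended on which control it was set against. The mean of the overexpression and knockdown effects called 95 genes, 51 up and 44 down. It also passes where 1 effect is large and the other is not: CALB1 (0.80) was called in both comparisons, PMCH (0.79) with overexpression alone, and MT1X (-1.61) and CXCL1 (-1.64) had effects of unequal size and opposite sign.

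Of the 4 groups, scrambled shRNA stood furthest apart: 283 genes were above and 376 below each of the 3 other groups in the limma tests. Empty vector had 39 and 62, overexpression 89 and 55, and knockdown 44 and 15. Above all others were 18 of 26 NF-kappaB targets in scrambled shRNA and 5 of 19 unfolded protein response genes in knockdown. It was hypothesised that overexpression raised a set of its own, larger than in any other group, without an opposite change in knockdown. The 89 genes above all others in overexpression arrays, led by PMCH, EVI2A and EGFL6, were fewer than the 283 in scrambled shRNA arrays, so the prediction failed as written. This count cannot decide whether overexpression raised a set of its own, since the change from scrambled shRNA to knockdown was not part of it. The groups ranked by these counts in a way the CXXC5 labels alone may not explain, and what sets the scrambled shRNA cells apart was not tested.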
